A study of Mus musculus with 13 samples.

How the data were processed

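Gene expression was measured on 13 single-colour microarrays with biotin-labelled targets, 4 from vehicle-treated, 4 from TCDD-treated and 5 from Cl-BBQ-treated host mice. Groups and replicate numbers were taken from the source descriptions in the labels, which call the samples biological replicates. The deposited table held log2 expression for 41345 probe sets per array. Per the submitters' processing notes the values were made with RMA, which corrects background, normalizes quantiles between arrays and summarizes probes into probe sets; its version, the software and the annotation are not given in the sources used here. The labels' protocol describes a one-cycle labelling kit with oligo-dT priming. Array medians lay between 4.27 and 4.33, and array-to-array correlations over all probe sets between 0.943 and 0.976, with no pair of identical arrays. Because quantile normalization forces a common distribution, a shift of all transcripts in one direction cannot be seen in these values.

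Probe sets were named through the platform annotation, with symbols updated by gene identifier to the mouse gene table of the GRCm38.p6 assembly. That annotation listed 25335 probe sets, of which 23521 had 1 symbol and 1814 several, and 16010 probe sets were unnamed here. Probe sets with several symbols named no gene. For each of 22180 genes the probe set with the highest mean over all arrays was used, and 1082 genes had more than 1 probe set. Genes above the median of all values (4.31) in at least 4 arrays were tested, which left 12710. Among called genes with further probe sets above the floor, 43 of 47 further sets had the same direction with TCDD and 79 of 84 with Cl-BBQ, and none of those in the opposite direction belonged to a gene named in the text. No coordinates are given, since the build behind the array design is not given in the sources used here.

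One limma model (version 3.58.1, R 4.3.3) with 3 group means was fitted to the log2 values with lmFit and eBayes, and the contrasts TCDD minus vehicle, Cl-BBQ minus vehicle and Cl-BBQ minus TCDD were tested two-sided. All 13 arrays shared one estimate of the spread, with 10 residual degrees of freedom and 4.22 prior ones. P-values were adjusted within each contrast by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. SE is the moderated standard error of a log2 difference, except where it is said to be taken over the members of a list. Intervals are 95% intervals from the same model. The named genes were, per contrast with vehicle, the 10 largest rises and 10 largest falls among called genes whose treated arrays all lay on one side of the vehicle arrays, leaving out predicted genes, clones and receptor segments. For the direct contrast the rule took the 8 largest each way. A fixed set of 30 genes was added whatever their result, as were up to 4 members of each gene list with the smallest adjusted p and any member needed to describe a list. The members named for that last reason, and the gene families set apart from the fixed lists, were chosen after their values had been seen.

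There were 33 gene lists, covering AhR targets, T cell states, pathways, proliferation and markers of other cell types, written from general knowledge before the data were examined, as were the groups, the tests of the 3 contrasts and of these lists, the rule for named genes and the alternatives, except what is said to have been chosen or added later. All tests of explanations other than chance splits of the arrays were chosen after the results had been seen. Of the listed genes, 43 had no probe set with a single symbol and were not analysed here. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 84 tests of lists and contrasts. Of these, 36 passed with the preset and 20 with the estimated correlation. Marker lists of other cell types were also compared as array means over all named members with exact two-sided permutation tests. A planned comparison of control probe sets at the ends of transcripts was not made, since no such probe sets were named, so RNA quality was not examined. Scan dates and slides were not used here.

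The pipeline was tested on simulated data with 12710 genes and the spread of the real arrays. With 50 changed genes per size, 40% of genes changed by 0.5 log2, 98% of those changed by 1 and all of those changed by 2 were recovered in the comparison of TCDD with vehicle, with 10 false calls among 179. For Cl-BBQ against vehicle the shares were 52% and 98%, and for the direct contrast 46% and 94%. Far fewer genes passed in the real direct contrast than in its simulation. The Benjamini-Hochberg adjustment is stricter when fewer genes pass. The shares of 46% and 94% therefore do not tell how many changes of these sizes the real direct contrast would recover. Of 100 unshifted lists, 2 passed an unadjusted p of 0.05. The simulated genes varied independently, so this does not test camera on lists whose genes vary together. The shared response was set against 100 simulations of unchanged groups, and against all 6 ways of giving each ligand its own pair of vehicle arrays. Another 100 simulations, added after the data had been seen, kept the changes of the genes called with Cl-BBQ and gave TCDD none.

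Alternatives were no filter or a stricter filter on dim probe sets, every probe set by itself, the mean of a gene's probe sets, repeated quantile normalization, median centring, eBayes with trend and robust options, array weights, the replicate number as a block, only the 2 groups compared, a fold of at least 1.5, an adjusted p under 0.01, an estimated list correlation, split vehicle arrays, and each array left out in turn. Leaving out Cl-BBQ replicate 1 and vehicle replicate 3 together was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.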

Results

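The series measured RNA in donor CD4+ T cells responding to host antigen in a mouse model of acute graft-versus-host disease, in which transferred donor T cells attack the tissues of the host. Splenocytes of C57BL/6 mice were labelled with CFSE, a dye diluted at every cell division, and transferred into B6D2F1 hosts. The hosts received TCDD, vehicle or Cl-BBQ, and alloresponding CD4+ cells that had divided at least 2 times were sorted from spleen and lymph node at 72 h. TCDD (dioxin) and Cl-BBQ are both ligands of the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor. TCDD was given at 15 µg/kg on day 0, Cl-BBQ at 10 mg/kg daily from day 0 to day 2 and vehicle on the same days as Cl-BBQ, so the ligands differ in dose and schedule, and TCDD also differs from vehicle in the days of treatment. There were 4 vehicle, 4 TCDD and 5 Cl-BBQ arrays, each described as a biological replicate. The deposited values were log2 expression per probe set after RMA, and array medians lay between 4.27 and 4.33. One probe set was kept for each of 22180 genes, and 12710 genes above the floor of 4.31, the median of all values, were tested. The precision of each value is limited by the number of arrays. The question, as far as the title of the series gives it, was how AhR signalling alters gene expression in newly activated CD4+ T cells.

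TCDD was compared with vehicle to find which transcripts the prototype ligand altered in the dividing donor cells. The largest rises included the granzyme genes Gzma and Gzmb, Il12rb2, the homing gene Gpr15 and the AhR target Cyp1b1, while genes of DNA replication and mitosis fell. Il12rb2, the signalling chain of the interleukin 12 receptor, went from 5.77 ± 0.33 (SD, n = 4) with vehicle to 10.24 ± 0.30 (SD, n = 4) with TCDD, a fold change of 22.1. Gzmb, which encodes the granule protease granzyme B, rose 12.7-fold, and Itgb1, the beta chain of many matrix-binding integrins, fell by 3.14 on the log2 scale. Foxp3, the transcription factor of regulatory T cells, was at 7.45 ± 0.21 with vehicle and 7.17 ± 0.34 with TCDD, which did not pass the test (limma, adjusted p = 0.45). In all, 853 of 12710 genes were called by limma with Benjamini-Hochberg adjustment, 408 higher and 445 lower with TCDD, and 219 of them changed at least 2-fold. All TCDD arrays lay on one side of all vehicle arrays for 13.6% of genes, against 2.86% by chance.

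The 10 largest rises with TCDD also included Gpr15, a receptor guiding T cells to the colon (log2 change 4.29 ± 0.23 SE), Gzma, encoding granzyme A (3.45 ± 0.18), and Pltp, a phospholipid transfer protein (3.55 ± 0.16). Asb2, a subunit of a ubiquitin ligase (3.27 ± 0.15), Cyp1b1, a cytochrome P450 of the AhR battery (3.20 ± 0.20), and Itgae, the integrin chain CD103 that binds epithelial E-cadherin (2.84 ± 0.18), rose as well. Cxcr6, a chemokine receptor of tissue-resident lymphocytes (2.76 ± 0.16), and Myo1f, an unconventional myosin (2.66 ± 0.11), completed them. For each of these 10 genes all 4 TCDD arrays were above all 4 vehicle arrays, and the largest adjusted p among them was 1.9e-07, for Itgae (limma). The vehicle means of Gpr15 (3.97) and Cyp1b1 (3.68), and among genes named below those of Ahrr, Cyp1a1 (3.90), Itga2 (4.20) and Ccr9 (4.06), lay below the floor, where array values compress differences.

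The largest falls with TCDD were those of Stfa3, a stefin-type protease inhibitor (log2 change -3.56 ± 0.33 SE), and Itgb1 (-3.14 ± 0.13). Nrp1, a co-receptor for semaphorins also used as a marker of thymus-derived regulatory T cells, fell by 2.87 on the log2 scale. Dapl1 (-2.59 ± 0.15), AB124611 (-2.55 ± 0.28) and Cybb, a subunit of the phagocyte oxidase (-2.15 ± 0.33), fell too. Cd22, a lectin best known as an inhibitory receptor of B cells, fell by 2.14, and Popdc2, Shcbp1 and the membrane protein gene Ms4a4c fell by 1.95, 1.90 and 1.89. All 4 TCDD arrays were below all 4 vehicle arrays for these 10 genes, and the largest adjusted p was 7.0e-04, for Cybb (limma). The TCDD means of Cd22 (4.03) and Popdc2 (4.12) lay below the floor.

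Among 7 tested AhR target genes, 6 rose with TCDD, and 6 when adjusted over the list alone. Cyp1b1, Cyp1a1 (log2 change 1.45 ± 0.27 SE), Tiparp, an ADP-ribosyltransferase (1.33 ± 0.14), Ahrr, the AhR repressor (1.27 ± 0.19), and the quinone reductase gene Nqo1 (1.01 ± 0.17) were among them. Camera, limma's test of a list against all other genes, gave an adjusted p of 3.0e-11, and an adjusted p of 0.013 with an estimated correlation. Ahr itself differed by 0.42 ± 0.19, which did not pass (limma, adjusted p = 0.27) except without TCDD replicate 4 (adjusted p = 0.041).

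Cytotoxic genes rose in 7 of 12 tested members, also 7 when adjusted over the list alone, with a median log2 change of 1.16 (camera, adjusted p = 1.3e-11, and adjusted p = 0.013 with an estimated correlation). They included the pore-forming protein gene Prf1 (1.97 ± 0.26 SE), the granule protein gene Nkg7 (1.96 ± 0.11) and Fasl, the ligand of the death receptor Fas (1.24 ± 0.22). The natural killer cell marker list, which holds Gzma too, had 4 tested members, and Gzma alone rose. Adjusted over the list alone, 1 rose as well. The other 3 had a mean change of 0.07 (camera for the whole list, adjusted p = 0.030, and adjusted p = 0.10 with an estimated correlation).

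Among Th1 genes, 7 of 15 tested members rose with TCDD, 9 when adjusted over the list alone (camera, adjusted p = 7.9e-11, and adjusted p = 0.010 with an estimated correlation). Besides Il12rb2, they held both chains of the interleukin 18 receptor, Il18rap (log2 change 1.88 ± 0.21 SE) and Il18r1 (1.10 ± 0.13), and the chemokine gene Ccl5 (0.97 ± 0.22). The call of Ccl5 was lost without TCDD replicate 3 (adjusted p = 0.0504), and that of Ccl4, also among the 7, without any one of 7 arrays, with an adjusted p of up to 0.089 without vehicle replicate 2. The effector cytokine genes themselves differed by less, with Ifng at 0.36 ± 0.20 (limma, adjusted p = 0.40), Tnf at -0.03 ± 0.23 (adjusted p = 0.97) and the Th1 transcription factor gene Tbx21 at 0.34 ± 0.15 (adjusted p = 0.26).

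Genes of type 1 regulatory cells, which are Foxp3-independent suppressor T cells, rose in 6 of 10 tested members, 9 when adjusted over the list alone, where 1 fell (camera, adjusted p = 4.3e-10, and adjusted p = 0.0053 with an estimated correlation). Il10, the suppressive cytokine, rose 3.29-fold, from 5.91 ± 0.23 with vehicle to 7.63 ± 0.16 with TCDD. Itga2, the integrin chain CD49b (log2 change 1.93 ± 0.18 SE), the transcriptional repressor gene Prdm1 (1.02 ± 0.22) and the inhibitory receptor gene Lag3 (0.62 ± 0.08) rose as well. Il21 was called too (log2 change 0.39, limma, adjusted p = 0.038), a call lost without any one of 7 arrays, with an adjusted p of up to 0.11 without TCDD replicate 2.

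Of 15 tested genes of the regulatory T cell signature, 4 rose and 1 fell, 5 and 3 when adjusted over the list alone, and the list did not pass as a set (camera, adjusted p = 0.10, and adjusted p = 0.29 with an estimated correlation). Itgae and Ctla4, an inhibitory receptor (log2 change 0.71 ± 0.10 SE), rose and Nrp1 fell. Il2ra, the high-affinity chain of the interleukin 2 receptor, and Tnfrsf18 were called as well, but these calls were lost without any one of 6 and 7 arrays, with adjusted p of up to 0.11 without vehicle replicate 4 and 0.10 without vehicle replicate 2. Coinhibitory receptors rose in 4 of 11 tested members and fell in 2, 6 and 2 when adjusted over the list alone. Havcr2, encoding TIM-3 (1.36 ± 0.29), Cd160 (0.77 ± 0.16), Ctla4 and Lag3 rose, while Pdcd1, encoding PD-1, was at -0.12 ± 0.15 and Tigit at 0.33 ± 0.10 without passing, except Tigit without Cl-BBQ replicate 1 (adjusted p = 0.043). The falls of Cd200 and Btla were lost without any one of 3 and 5 arrays, with adjusted p of up to 0.065 without vehicle replicate 1 and 0.098 without vehicle replicate 2. As a set the coinhibitory receptors passed (camera, adjusted p = 0.025), with adjusted p = 0.26 with an estimated correlation, and they did not pass without TCDD replicate 1 or vehicle replicate 3 (adjusted p of 0.055 and 0.054).

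Chemokine receptor and homing genes rose in 7 of 17 tested members and fell in 2, 9 and 3 when adjusted over the list alone (camera, adjusted p = 5.0e-06, and adjusted p = 0.039 with an estimated correlation). Ccr9, which guides lymphocytes to the small intestine (log2 change 1.61 ± 0.23 SE), Ccr4 (2.82-fold) and Ccr2 (2.83-fold) rose beside Gpr15, Cxcr6 and Itgae. Itga4, a chain of the integrins that bind VCAM-1 and MAdCAM-1, fell by 1.13 on the log2 scale. The other fall, of Cxcr4, was lost without vehicle replicate 1 (adjusted p = 0.052). Ccr7, the lymph node homing receptor, was at -0.43 ± 0.18 (limma, adjusted p = 0.22), but was called without vehicle replicate 3 (adjusted p = 0.017).

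All 19 tested genes of the G2 and M phases fell with TCDD, 19 when adjusted over the list alone, with a median log2 change of -1.15 (camera, adjusted p = 9.7e-34, and adjusted p = 0.0053 with an estimated correlation). Bub1b, a kinase of the spindle checkpoint (-1.33 ± 0.12 SE), Top2a, a DNA topoisomerase (-1.30 ± 0.12), and the proliferation marker Mki67 (-1.08 ± 0.18) were among them. Of 16 tested S phase genes 13 fell and none rose, 14 when adjusted over the list alone, among them both subunit genes of ribonucleotide reductase, Rrm1 (-1.25 ± 0.12) and Rrm2 (-1.09 ± 0.13) (camera, adjusted p = 1.1e-19, and adjusted p = 0.010 with an estimated correlation). Cd4, a marker of the sorted cells, was at 0.06 ± 0.10 in the same comparison.

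Activation genes rose in 3 of 17 tested members and fell in 1, 4 and 1 when adjusted over the list alone, with Cd69 (log2 change 1.12 ± 0.11 SE) and Tnfrsf9, encoding the costimulator 4-1BB (1.12 ± 0.15), leading (camera, adjusted p = 4.7e-05, and adjusted p = 0.016 with an estimated correlation). The fall, of Irf4, was lost without any one of 8 arrays, with an adjusted p of up to 0.10 without TCDD replicate 4. Of 13 tested apoptosis and p53 genes, 3 rose and 1 fell, the same numbers when adjusted over the list alone. They were Bcl2l11, which encodes the death-promoting protein BIM (1.00 ± 0.16), the cell cycle inhibitor Cdkn1a (1.05 ± 0.22) and Fasl, with the survival gene Bcl2 at -0.84 ± 0.15. All 4 TCDD arrays lay on one side of all vehicle arrays for these genes except Cdkn1a. The set passed with the preset correlation (camera, adjusted p = 0.040), with adjusted p = 0.16 with an estimated correlation, and not without TCDD replicate 2 or vehicle replicates 1 or 3 (adjusted p of 0.077, 0.0501 and 0.054). Cholesterol synthesis genes rose in 3 of 14 tested members, 6 when adjusted over the list alone (camera, adjusted p = 0.0049, and adjusted p = 0.16 with an estimated correlation). These 3, Hmgcs1, Mvd and Sqle, were each lost without some single arrays, with adjusted p of up to 0.098 without vehicle replicate 4, and 0.12 and 0.099 without vehicle replicate 2. Th2 genes rose in 2 of 7, 3 when adjusted over the list alone (camera, adjusted p = 0.034, and adjusted p = 0.21 with an estimated correlation), led by Ccr4 and the interleukin 4 receptor gene Il4ra (0.83 ± 0.11), and the set did not pass without TCDD replicate 2 or vehicle replicates 3 or 4 (adjusted p of 0.062, 0.054 and 0.065).

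None of 16 tested interferon-stimulated genes was called with TCDD by limma, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, and their median log2 change was 0.06 (camera, adjusted p = 0.60). Without TCDD replicate 2 the same list passed camera (adjusted p = 0.029). The follicular helper list had 1 higher and 2 lower of 11, 2 and 3 when adjusted over the list alone (camera, adjusted p = 0.35), and Pou2af1, a transcriptional coactivator, fell by 1.17 on the log2 scale. Naive and memory genes had 3 higher and 1 lower of 13, 4 and 1 when adjusted over the list alone (camera, adjusted p = 0.26). Of 16 secreted cytokine genes 3 rose, 4 with 1 fall when adjusted over the list alone, and of 12 TGF-beta pathway genes 1 rose either way. Of 13 glycolysis genes Slc2a1 and Slc2a3 rose, 2 when adjusted over the list alone too, but these calls were lost without any one of 5 and 9 arrays, with adjusted p of up to 0.082 without TCDD replicate 1 and 0.14 without vehicle replicate 2. Of 8 NRF2 targets 1 rose, 2 with 1 fall when adjusted over the list alone. No gene of the unfolded protein response (12 tested) or of the Th17 and Th22 list (4 tested) was called by limma, over all genes or adjusted over the list alone, with 2 and 1 at an unadjusted p under 0.05. None of these sets passed, with camera adjusted p between 0.11 and 0.88. For glycolysis the median was -0.03 and the mean 0.02, and for the TGF-beta pathway the median was -0.01, of the opposite sign after quantile normalization, and the mean 0.10. Il22 had means of 1.43 with vehicle, 1.58 with TCDD and 1.56 with Cl-BBQ, below the floor.

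**Figure D1:**
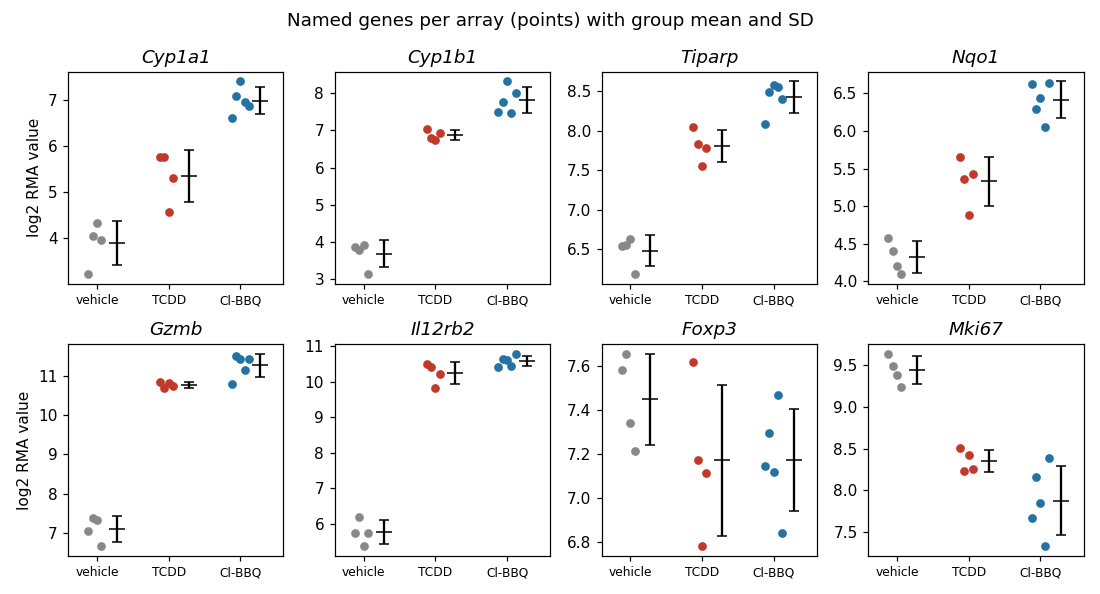
Log2 RMA values of 8 genes in each array, with vehicle in grey, TCDD in red and Cl-BBQ in blue; the bar beside each group of points marks the mean and its whiskers 1 SD, and each panel has its own vertical scale that does not start at 0. The AhR targets Cyp1b1, Tiparp and Nqo1 were higher with either ligand than with vehicle, while the Foxp3 values of the groups overlapped.

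Cl-BBQ was compared with vehicle to find which transcripts the other ligand altered in the same cell population. The largest rises again included Gzma, Gzmb, Il12rb2, Gpr15 and Cyp1b1, and proliferation genes again fell. Il12rb2 went from 5.77 ± 0.33 (SD, n = 4) with vehicle to 10.58 ± 0.15 (SD, n = 5) with Cl-BBQ, a log2 change of 4.81 ± 0.16 SE. Gzma rose 25.2-fold, Cyp1b1 17.6-fold and Gzmb 17.9-fold. Foxp3 was at 7.17 ± 0.23 with Cl-BBQ and did not pass (limma, adjusted p = 0.35). In all, 1441 of 12710 genes were called by limma with Benjamini-Hochberg adjustment, 675 higher and 766 lower, and 363 of them changed at least 2-fold. All Cl-BBQ arrays lay on one side of all vehicle arrays for 12.9% of genes, against 1.59% by chance.

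Il12rb2, Gpr15 (log2 change 4.59 ± 0.22 SE), Gzmb (4.16 ± 0.16), Gzma (4.66 ± 0.17), Pltp (3.93 ± 0.15), Cyp1b1 (4.14 ± 0.19), Asb2 (3.46 ± 0.14) and Itgae (3.09 ± 0.17) were in the 10 largest rises, as they were with TCDD. The other 2 were Ifitm3, an interferon-inducible membrane protein that restricts virus entry (3.15 ± 0.18), and Cyp1a1, the classic AhR-induced cytochrome P450 (3.08 ± 0.26). All 5 Cl-BBQ arrays were above all 4 vehicle arrays for these 10 genes, and the largest adjusted p was 1.3e-06, for Cyp1a1 (limma). The largest falls were those of Stfa3 (-4.60 ± 0.32), Itgb1 (-3.23 ± 0.13), Dapl1 (-2.91 ± 0.14), AB124611 (-2.89 ± 0.26), Nrp1 (-2.87 ± 0.20) and Gpm6b, a neuronal-type membrane protein gene (-2.79 ± 0.27). Cybb (-2.48 ± 0.31), Ms4a4c (-2.25 ± 0.27), H1f1, a linker histone gene (-2.25 ± 0.31), and Gstp3, a glutathione transferase gene (-2.11 ± 0.13), followed. All 5 Cl-BBQ arrays were below all vehicle arrays for these genes, and the largest adjusted p was 1.4e-04, for H1f1 (limma). The vehicle means of Gpr15 (3.97), Cyp1b1 (3.68) and Cyp1a1 (3.90) and the Cl-BBQ means of Stfa3 (3.60) and Cybb (4.11) lay below the floor, so the sizes of these changes are compressed.

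With Cl-BBQ, 6 of 7 tested AhR targets rose, 7 when adjusted over the list alone, with a median log2 change of 1.94 (camera, adjusted p = 2.8e-13, and adjusted p = 0.010 with an estimated correlation). Tiparp changed by 1.94 ± 0.13 SE, Nqo1 by 2.09 ± 0.16 and Ahrr by 1.49 ± 0.18, and Ahr did not pass at 0.28 ± 0.18 (limma, adjusted p = 0.41). Cytotoxic genes rose in 7 of 12, also 7 when adjusted over the list alone (camera, adjusted p = 2.8e-10, and adjusted p = 0.016 with an estimated correlation), with Prf1 at 2.31 ± 0.25 and Nkg7 at 2.21 ± 0.11. Of 4 tested natural killer cell markers Gzma alone rose, 1 with 1 fall when adjusted over the list alone, and the other 3 had a mean change of 0.04. As a set these markers did not pass (camera, adjusted p = 0.055), but did without Cl-BBQ replicate 3 or vehicle replicate 4 (adjusted p of 0.012 and 0.034).

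Th1 genes rose in 10 of 15 tested members with Cl-BBQ, 12 when adjusted over the list alone (camera, adjusted p = 7.9e-11, and adjusted p = 0.010 with an estimated correlation). Il18rap changed by 2.44 ± 0.20 SE on the log2 scale, Il18r1 by 1.57 ± 0.13 and Tbx21 by 0.64 ± 0.15 (limma, adjusted p = 0.0088), while Ifng was at 0.61 ± 0.19 (adjusted p = 0.059) and was called without vehicle replicate 1 (adjusted p = 0.0068) or Cl-BBQ replicate 3 (adjusted p = 0.036). The call of Cxcr3, also among the 10, was lost without vehicle replicates 2 or 3 (adjusted p of 0.071 and 0.070). Type 1 regulatory cell genes rose in 6 of 10, 6 when adjusted over the list alone, led by Gzmb, Itga2 (2.51 ± 0.17), Il10 (1.80 ± 0.14) and Prdm1 (1.13 ± 0.21) (camera, adjusted p = 5.6e-07, and adjusted p = 0.010 with an estimated correlation). Il21 was at -0.06 ± 0.10 (limma, adjusted p = 0.79).

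Of 15 tested genes of the regulatory T cell signature, 6 rose and 3 fell with Cl-BBQ, 7 and 3 when adjusted over the list alone, with Itgae, Ctla4 (log2 change 0.81 ± 0.09 SE) and Il2ra (0.97 ± 0.17) up and Nrp1 down. The list lay at the edge of the threshold (camera, adjusted p = 0.050), with adjusted p = 0.23 with an estimated correlation. It did not pass without Cl-BBQ replicates 2 or 4, TCDD replicates 1 or 2, or vehicle replicates 3 or 4, with an adjusted p of up to 0.099 without vehicle replicate 4. Ikzf2, encoding the transcription factor Helios, was lower by -0.56 ± 0.14 (limma, adjusted p = 0.016), a call lost without any one of 3 arrays, with an adjusted p of up to 0.058 without vehicle replicate 1. Coinhibitory receptors rose in 5 of 11 and fell in 2, 6 and 4 when adjusted over the list alone (camera, adjusted p = 0.11). Havcr2 changed by 1.56 ± 0.27, Cd200 by -0.74 ± 0.10 and Btla by -0.59 ± 0.10, and Pdcd1 was at -0.42 ± 0.14 (limma, adjusted p = 0.082), called without TCDD replicate 3 (adjusted p = 0.041).

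Homing genes rose in 9 of 17 tested members and fell in 2, 10 and 2 when adjusted over the list alone (camera, adjusted p = 3.7e-06, and adjusted p = 0.038 with an estimated correlation), with Ccr9 at 1.89 ± 0.22 SE, Ccr4 at 1.81 ± 0.19 and Ccr2 at 1.78 ± 0.13 on the log2 scale. Itga4 fell by 1.03 and Cxcr4, the receptor for CXCL12, by 0.80. All 19 tested G2 and M phase genes fell, 19 when adjusted over the list alone, with a median of -1.53 (camera, adjusted p = 9.7e-34, and adjusted p = 0.0053 with an estimated correlation), Mki67 by 1.56 and Top2a by 1.64. S phase genes fell in 14 of 16, 15 when adjusted over the list alone, with a median of -0.99 (camera, adjusted p = 2.9e-19, and adjusted p = 0.010 with an estimated correlation). Cd4 was at 0.06 ± 0.09.

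Cholesterol synthesis genes rose in 8 of 14 tested members with Cl-BBQ, 9 when adjusted over the list alone (camera, adjusted p = 1.9e-06, and adjusted p = 0.025 with an estimated correlation). Hmgcs1, the enzyme that makes HMG-CoA, changed by 0.65 ± 0.11 SE on the log2 scale, Mvd by 0.63 ± 0.12 and Cyp51 by 0.63 ± 0.14, while the call of Insig1 was lost without any one of 5 arrays, with an adjusted p of up to 0.11 without vehicle replicate 3. Activation genes rose in 5 of 17 and fell in 1, 11 and 1 when adjusted over the list alone (camera, adjusted p = 2.4e-05, and adjusted p = 0.015 with an estimated correlation), with Cd69 at 1.40 ± 0.11 and Myc at 0.73 ± 0.14. Apoptosis and p53 genes rose in 3 of 13 and fell in 1, the same numbers when adjusted over the list alone (camera, adjusted p = 0.045, and adjusted p = 0.16 with an estimated correlation). The set was past the threshold or not depending on single arrays, with an adjusted p of up to 0.083 without Cl-BBQ replicate 3. Follicular helper genes rose in 1 of 11 and fell in 4, 1 and 5 when adjusted over the list alone, Pou2af1 by 1.37 and the follicular helper transcription factor gene Bcl6 by 0.73 (camera, adjusted p = 0.013, and adjusted p = 0.21 with an estimated correlation). The rise, of Icos, also counted among activation and type 1 regulatory cell genes, was lost without any one of 11 arrays, with an adjusted p of up to 0.10 without vehicle replicate 1. No interferon-stimulated gene of 16 was called by limma, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05, and the median was 0.03 (camera, adjusted p = 0.67).

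Naive and memory genes rose in 4 of 13 tested members and fell in 2 with Cl-BBQ, the same numbers when adjusted over the list alone (camera, adjusted p = 0.20), with the interleukin 7 receptor gene Il7r at 2.53 ± 0.17 SE on the log2 scale. Secreted cytokine genes rose in 2 of 16 and fell in 2, 3 and 3 when adjusted over the list alone, with a median of -0.03 and a mean of 0.15. Il4 was at -0.82 ± 0.20 (limma, adjusted p = 0.015), a call lost without vehicle replicate 2 (adjusted p = 0.056). Th2 genes had 3 higher and 1 lower of 7, NRF2 targets 2 and 1 of 8, glycolysis genes 2 and 0 of 13, and the unfolded protein response 1 and 0 of 12, the same numbers when adjusted over the list alone. Of the Th2 genes, Gata3 lost its call without any one of 7 arrays, with an adjusted p of up to 0.11 without vehicle replicate 3. TGF-beta pathway genes had 1 higher and 0 lower of 12, 2 and 0 when adjusted over the list alone. No Th17 or Th22 gene of 4 was called by limma, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05. None of these sets passed, with camera adjusted p between 0.11 and 0.78. For glycolysis the median was -0.10 and the mean 0.05, and for the TGF-beta pathway they were -0.03 and 0.09.

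**Figure D2:**
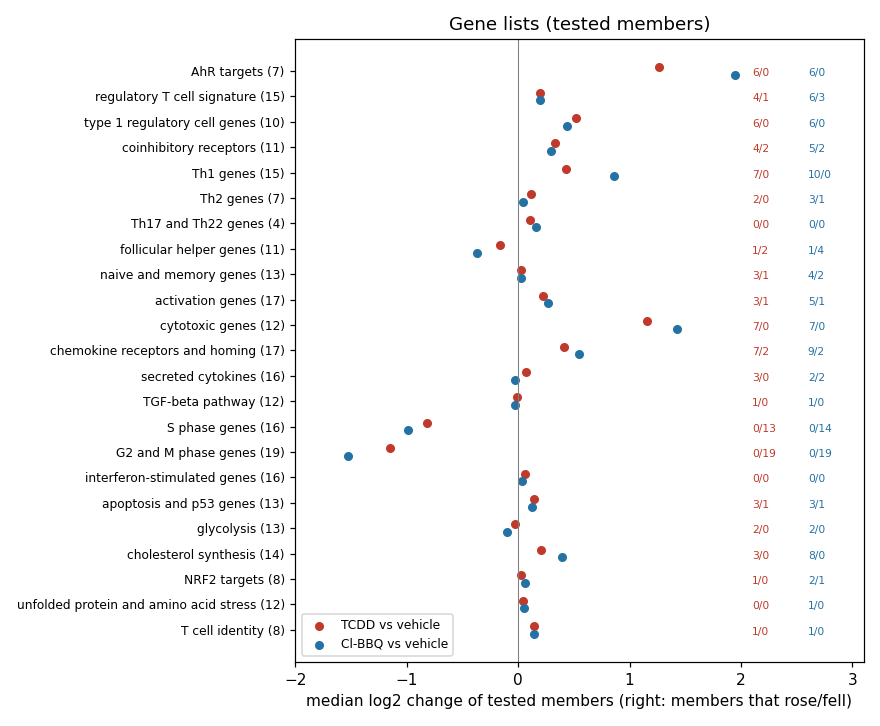
Median log2 change against vehicle of the tested members of each gene list, with TCDD in red and Cl-BBQ in blue; the number of tested members stands in parentheses and the numbers of members that rose and fell stand at the right. The G2 and M phase list lay lowest, at -1.15 and -1.53, and the AhR target list highest, at 1.27 and 1.94.

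Markers of T cells and of other cell types were measured in the same arrays, as means over all named members of a list. The T cell identity list had a mean of 11.04 ± 0.10 (SD, n = 4) with vehicle, 11.18 ± 0.02 with TCDD and 11.20 ± 0.05 with Cl-BBQ. The differences were 0.15 (exact two-sided permutation test, p = 0.029, the smallest possible for 4 against 4) and 0.16 (exact p = 0.0079, the smallest possible for 5 against 4). Camera called this list in both comparisons (adjusted p = 0.020), with adjusted p = 0.36 with an estimated correlation. Without vehicle replicate 3 the camera adjusted p was 0.12 with TCDD and 0.11 with Cl-BBQ. Of 8 tested members Zap70, a kinase of the T cell receptor, was the single one called, 1 with TCDD and 2 with Cl-BBQ when adjusted over the list alone. Its call was lost without some arrays, with adjusted p of up to 0.099 without TCDD replicate 1 for TCDD and 0.081 without vehicle replicate 3 for Cl-BBQ.

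B cell markers differed by -0.21 with TCDD (exact p = 0.029) and by -0.13 with Cl-BBQ (exact p = 0.0079), and natural killer cell markers, which hold Gzma, by 0.59 and 0.79 with the same p. After adjustment over the 33 tests of this kind no list passed, and T cell identity, B cell and natural killer cell markers had adjusted p of 0.13 with TCDD and 0.087 with Cl-BBQ. Of 7 tested B cell markers Cd22 alone fell with each ligand, also when adjusted over the list alone. The median of these 7 with TCDD was 0.00, of the opposite sign after quantile normalization or median centring, and their mean was -0.27 (camera, adjusted p = 0.38 with TCDD and 0.67 with Cl-BBQ). Myeloid markers differed by -0.01 and 0.01, and dendritic cell and MHC class II markers by 0.01 and 0.06, with exact p of 0.59 or more. Over the 6 myeloid markers above the floor alone the means were 0.19 and 0.22 (camera, adjusted p = 0.21 and 0.13), with 1 and 2 higher, and 2 and 2 when adjusted over the list alone. Cd68, a lysosomal protein of macrophages, rose with TCDD (log2 change 0.79 ± 0.20 SE) and Cl-BBQ (0.64 ± 0.19), but these calls were lost without any one of 5 and 7 arrays, with adjusted p of up to 0.081 and 0.13 without vehicle replicate 3. The other call with Cl-BBQ, Tyrobp, was lost without any one of 5 arrays, with an adjusted p of up to 0.077 without vehicle replicate 4. CD8 T cell markers differed by 0.16 with TCDD (exact p = 0.37) and by 0.37 with Cl-BBQ (exact p = 0.016, adjusted p = 0.13). Plasma cell markers differed by 0.11 and 0.10, platelet markers by 0.08 and -0.06, and erythroid markers by 0.04 and -0.17, with exact p of 0.20 or more. Immediate early and heat shock genes, which respond to handling, differed by 0.02 and 0.13 (exact p = 0.77 and 0.17), and of 10 tested Fos alone was called, with Cl-BBQ, also when adjusted over the list alone.

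The responses to both ligands were set side by side across genes, which are not independent replicates. Genes called higher with both numbered 373 of the 408 called higher with TCDD, where independent lists would share 21.7, and 404 of the 445 called lower, where independent lists would share 26.8. Simulations that kept the Cl-BBQ changes and the shared vehicle arrays but no TCDD effect gave at most 1 gene called in the same direction with both. No gene was called in opposite directions by limma, as in every simulation. Of the 1739 genes at an unadjusted p under 0.05 with both ligands 0 went in opposite directions, against a mean of 32.5 of 201 in the simulations. The correlation of the log2 changes was 0.890 across 12710 genes, but both use the same vehicle arrays, and simulated unchanged groups gave 0.527. With the vehicle arrays split so that each ligand had its own pair, it was 0.708. The covariance was 0.108, against 0.0124 in simulated unchanged groups, a difference of 0.0956, and 0.0951 with split vehicle arrays.

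**Figure D3:**
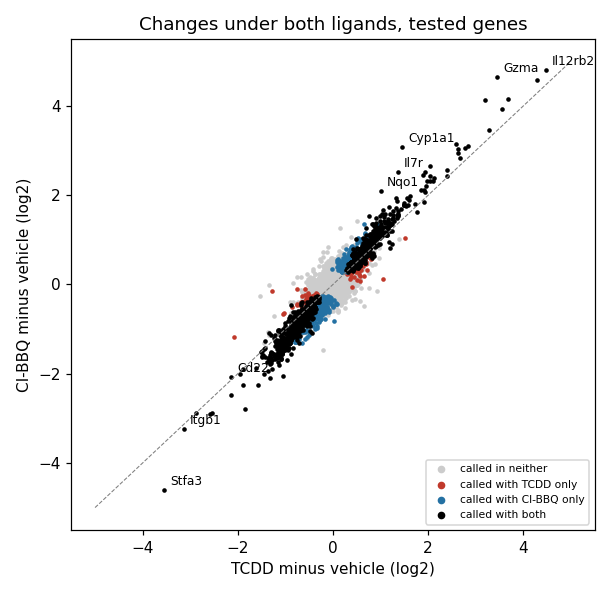
Log2 change with Cl-BBQ against log2 change with TCDD for each of 12710 tested genes, both relative to vehicle; black points were called with both ligands, red with TCDD only, blue with Cl-BBQ only and grey with neither, and the dashed line marks equal change. The called genes lie along the line, with Gzma, Il7r, Nqo1 and Cyp1a1 above it.

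Cl-BBQ was then compared with TCDD directly. Gzma (log2 difference 1.21 ± 0.17 SE), Il7r (1.16 ± 0.17) and Nqo1 (1.08 ± 0.16) were higher with Cl-BBQ, and they were the only genes called of 12710 (limma, adjusted p = 0.039 for each). For each of the 3 genes all 5 Cl-BBQ arrays were above all 4 TCDD arrays. Another 2 genes just missed the threshold, Cyp1a1 at 1.63 higher (95% interval 1.08 to 2.18) and Gstp3 at -0.79 (-1.06 to -0.52), both with an adjusted p of 0.051. At an unadjusted p under 0.05 there were 815 genes, where chance alone gives a share of about 0.05 of the 12710. All Cl-BBQ arrays lay on one side of all TCDD arrays for 2.11% of genes, against 1.59% by chance. The count of 3 calls was fragile and went to 0 without any one of the TCDD arrays, without Cl-BBQ replicates 2, 3 or 5, or without vehicle replicate 4. It was 5 without vehicle replicate 3, 0 with no filter on dim probe sets, with every probe set tested by itself or with the 2 groups alone in the model, and 7 with a stricter filter or with array weights. Across all settings tried the adjusted p of Gzma lay between 0.0088 and 0.245. Its log2 difference lay between 1.09 and 1.32 in them, that of Il7r between 1.10 and 1.26 and that of Nqo1 between 0.93 and 1.19.

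As sets, AhR targets were higher with Cl-BBQ than with TCDD by a median of 0.62 (camera, adjusted p = 9.5e-12, and adjusted p = 0.012 with an estimated correlation), with 1 of 7 members called and 5 when adjusted over the list alone. G2 and M phase genes were lower with Cl-BBQ by a median of -0.34 (camera, adjusted p = 4.3e-16, and adjusted p = 0.016 with an estimated correlation), with 0 of 19 called by limma over all genes and 16 when adjusted over the list alone. Cholesterol synthesis genes were higher by a median of 0.20 (camera, adjusted p = 6.9e-06, and adjusted p = 0.033 with an estimated correlation), with 0 of 14 called by limma either way and 4 at an unadjusted p under 0.05. The camera calls for Th1, cytotoxic, homing, follicular helper, S phase and NRF2 lists were not kept with an estimated correlation, where adjusted p lay between 0.083 and 0.25, and the NRF2 call (adjusted p = 0.039) was also lost without Cl-BBQ replicates 3 or 5, TCDD replicate 4 or vehicle replicate 3, with an adjusted p of up to 0.245 without TCDD replicate 4.

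For most genes the difference between the ligands was bounded. Of 1517 genes called with either ligand, 1476 (97.3%) had a 95% interval of Cl-BBQ minus TCDD within -1 and 1 on the log2 scale. These bounds are wide, since the median SE of this contrast over the tested genes was 0.129. Only 219 of the 853 genes called with TCDD and 363 of the 1441 called with Cl-BBQ changed by as much. For the others the bounds do not tell a like response from none with one ligand. The interval was -0.01 to 0.69 for Il12rb2, 0.14 to 0.84 for Gzmb, -0.22 to 0.38 for Il10 and -0.35 to 0.35 for Foxp3. Of the 664 genes called with Cl-BBQ and not with TCDD, 658 (99.1%) had the same sign with TCDD, against 55.6% in the simulations without a TCDD effect. The simulated share is over a mean of 1276 genes that include the largest Cl-BBQ changes, so the sets are not alike. Of the 664, 0 were called in the direct comparison by limma, with 151 at an unadjusted p under 0.05. Choosing genes that passed with Cl-BBQ and not with TCDD by itself favours a difference between the ligands. Il21, called with TCDD and not with Cl-BBQ, differed by -0.46 (95% interval -0.67 to -0.24, limma, adjusted p = 0.39), and Il4 differed by -0.85 (-1.29 to -0.42, adjusted p = 0.43).

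Over the 853 genes called with TCDD, each array was given a response score, the mean log2 difference from vehicle with the sign of the TCDD change. The score was 0.841 ± 0.013 (SD, n = 4) with TCDD and 0.966 ± 0.028 (SD, n = 5) with Cl-BBQ, a ratio of 1.15. All 5 Cl-BBQ arrays were above all 4 TCDD arrays (exact two-sided permutation test, p = 0.0079, the smallest possible), and 627 of the 853 genes (73.5%) had the larger change with Cl-BBQ. The score was not among the planned tests. The genes were chosen by their change with TCDD, which favours a high score with TCDD. They and their signs were not chosen anew for each assignment of the arrays, so the permutation test does not cover that choice. Dose and schedule differed together with the ligand.

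**Figure D4:**
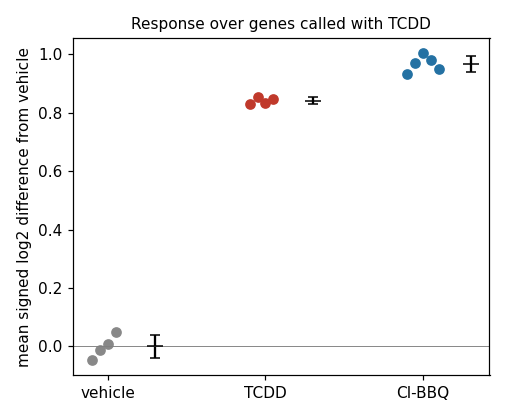
Response score per array, the mean log2 difference from the vehicle mean over the 853 genes called with TCDD, each gene signed by its change with TCDD; points are arrays, bars are group means and whiskers 1 SD. The Cl-BBQ arrays lie above the TCDD arrays, with means of 0.966 and 0.841.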

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

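All tests of explanations here were chosen after the results had been seen, and the counts of other splits of the arrays were planned before. The fall of proliferation genes was weighed first, 32 of the 35 tested S, G2 and M phase genes with TCDD and 33 with Cl-BBQ. Dilution by cells other than CD4 T cells would lower Cd4 along with the proliferation genes, and the lower 95% limit of its change was -0.14 against a median of -1.15 for the G2 and M phase list with TCDD, which argues against it as the whole cause. Without the 2 noisiest arrays, Cl-BBQ replicate 1 and vehicle replicate 3, 31 of these genes were still lower with TCDD and 33 with Cl-BBQ. Undivided naive T cells stay open as a source, although the sort on CFSE dilution would remove such cells. The naive and memory list mean plus 2 SE over its members was 0.394 with TCDD and 0.657 with Cl-BBQ, and its members went both ways. That SE measures the spread over genes, which are not independent, and not the spread between animals. Slower division under the ligands is a candidate explanation that was not tested.

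Transcripts best known from B cells and myeloid cells, Cd22 and Cybb, were among the largest falls. Fewer B or myeloid cells in the treated sorts would lower the other markers too, but of the 16 tested B cell, myeloid and dendritic cell markers other than Cd22 only Ighm, Cd68, Cst3 and Ctss lay at least 2 log2 above the floor with vehicle. The means of these 4 changed by 0.27 with TCDD and 0.26 with Cl-BBQ, and the lower of both minus 2 SE over the 4 members was -0.104. This SE too measures the spread over genes and not between animals. They are too few to exclude this explanation, although all 16 together had mean changes of 0.10 and 0.15, most of them near the floor. It stays open, although the sort of CD4+ cells that had divided at least 2 times would remove B and myeloid cells. Regulation of Cd22 and Cybb within the T cells is a candidate explanation that was not tested.

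The larger response to Cl-BBQ than to TCDD was weighed last, a gap of 0.0765 between the lowest Cl-BBQ and the highest TCDD response score. Of the 2 noisiest arrays, vehicle replicate 3 enters all scores alike, and Cl-BBQ replicate 1 differed from the mean of the other Cl-BBQ arrays by -0.0433, with an SD of 0.0230 among these, which argues against noise in it as what raised the group. After quantile normalization or median centring the gap was at least 0.0689, but these moved no score by more than 0.00939, less than the SD of the Cl-BBQ scores of 0.0278, so scaling stays open. The ligand, its dose and its schedule cannot be told apart by the design, and none of them was tested.

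Of all 35 splits of the TCDD and vehicle arrays, 1, the real one, gave as many as 853 called genes, and the highest other gave 0. Of 100 splits drawn for Cl-BBQ and vehicle, 1 gave as many as 1441, the real one, and the highest other gave 629. For Cl-BBQ and TCDD 1 of 100 gave as many as 3, the real one, and the highest other gave 2. A chance split of the arrays was thereby excluded at the level of 0.05 for all 3 counts, although the direct count of 3 is itself fragile to single arrays.

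Single arrays stood apart from their group in 27 of 435 groups examined, over 145 measures and genes, where chance gives about 1 in 20. The gap is the distance to the nearest other array divided by the whole range of the group. The residual SD of Cl-BBQ replicate 1 was 0.305 on the log2 scale, against 0.196 to 0.214 in the others of its group (gap 0.833). Its mean correlation with its own group over the tested genes was 0.971, against 0.980 to 0.982 (gap 0.862). For the regulatory T cell signature the mean was 7.27 in Cl-BBQ replicate 1 and 7.48 to 7.50 in the others (gap 0.901). For follicular helper genes the mean was 8.47 in vehicle replicate 3 and 8.65 to 8.68 in the others (gap 0.857). In Cl-BBQ replicate 2 the same mean was 8.17, and it was 8.27 to 8.30 in the others (gap 0.793). Cytotoxic genes had a mean of 5.79 in vehicle replicate 3 and 5.62 to 5.65 in the others (gap 0.831). For chemokine receptor and homing genes the mean was 7.22 in TCDD replicate 1 and 7.11 to 7.12 in the others (gap 0.887). In Cl-BBQ replicate 1 that mean was 7.10, and it was 7.27 to 7.33 in the others (gap 0.737). S phase genes had a mean of 7.29 in Cl-BBQ replicate 1 and 7.16 to 7.20 in the others (gap 0.725). For T cell identity the mean was 10.88 in vehicle replicate 3 and 11.07 to 11.11 in the others (gap 0.833).

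Gpr15 was at 4.77 in vehicle replicate 2 and between 3.62 and 3.76 in the others (gap 0.884). AB124611 was at 5.47 in TCDD replicate 2 and between 6.68 and 6.78 in the others (gap 0.926). Ms4a4c was at 6.47 in TCDD replicate 4 and between 5.47 and 5.54 in the others (gap 0.927). Il10 was at 5.57 in vehicle replicate 2 and between 5.97 and 6.05 in the others (gap 0.833). Prdm1 was at 6.10 in vehicle replicate 1 and between 5.46 and 5.54 in the others (gap 0.880). Il21 was at 9.24 in TCDD replicate 3 and between 9.52 and 9.56 in the others (gap 0.883). Il2 was at 6.85 in Cl-BBQ replicate 1 and between 6.00 and 6.23 in the others (gap 0.732). Il18r1 was at 5.77 in vehicle replicate 3 and between 6.08 and 6.12 in the others (gap 0.885). Il18r1 was at 6.95 in TCDD replicate 2 and between 7.15 and 7.18 in the others (gap 0.871). Itga4 was at 7.46 in TCDD replicate 4 and between 7.21 and 7.23 in the others (gap 0.903). Bcl2l11 was at 7.29 in Cl-BBQ replicate 1 and between 7.92 and 8.04 in the others (gap 0.839). Slc2a1 was at 8.35 in Cl-BBQ replicate 1 and between 7.94 and 8.05 in the others (gap 0.736). Tnfrsf18 was at 8.73 in vehicle replicate 2 and between 8.97 and 8.99 in the others (gap 0.917). Ikzf2 was at 8.43 in vehicle replicate 3 and between 9.08 and 9.10 in the others (gap 0.960). Cd4 was at 10.27 in vehicle replicate 3 and between 10.58 and 10.63 in the others (gap 0.866). Tyrobp was at 6.28 in TCDD replicate 4 and between 5.71 and 5.80 in the others (gap 0.841). Isg15 was at 8.66 in TCDD replicate 2 and between 9.16 and 9.22 in the others (gap 0.894).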

How the results depend on the processing

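Leaving out the 2 noisiest arrays, Cl-BBQ replicate 1 and vehicle replicate 3, was chosen after the data had been seen, and the other alternatives were planned. The 853 genes called with TCDD became 566 with a fold of at least 1.5, 473 with an adjusted p under 0.01 and 644 to 955 with single arrays left out. The 1441 called with Cl-BBQ became 835, 891 and 1185 to 1433. The 3 genes called between the ligands became 0 with no filter on dim probe sets, with every probe set tested by itself, with the 2 groups alone, with the replicate block and with an adjusted p under 0.01, and 1 without the 2 noisiest arrays. They became 5 with the mean of a gene's probe sets or repeated quantile normalization, 6 with trend and robust options, 7 with a stricter filter or array weights, and 0 to 5 with single arrays left out. Fewer genes pass a stricter threshold by construction. With no filter or every probe set by itself, the log2 differences of the 3 genes called between the ligands were unchanged. There the tests adjusted over rose from 12710 to 22180 and 22194, and the shared estimate of the spread was fitted anew. Which of these removed the calls was not tested, nor was the cause of the other changes. The correlation of both responses, 0.890, was 0.708 with split vehicle arrays, 0.828 with no filter and 0.871 to 0.898 with single arrays left out. The 36 gene list calls became 20 with an estimated correlation and 28 to 37 with single arrays left out.

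Without the 2 noisiest arrays the counts were 850 with TCDD and 1263 with Cl-BBQ, the correlation 0.896 and the list calls 30. The replicate number was not taken as a pairing, since the labels do not state that it pairs animals. Arrays of the same replicate number did not deviate together, with correlations between -0.0594 and 0.0751 and 0 of 12 pairs over 0.1. Only the Cl-BBQ group has a replicate 5, so a block on the number also leaves that array out of the comparisons. With the replicate number as a block there were 714, 1114 and 0 calls and 31 list calls. Every other alternative kept these counts within 1.5 times. No result changed sign past its threshold under any alternative. Counted over all pairs of a named gene and an alternative, a call was lost in 135 pairs with TCDD, 74 with Cl-BBQ and 42 between ligands, and gained in 34, 18 and 14. Over pairs of a gene list and an alternative, a call was lost in 22, 22 and 13, and gained in 1, 2 and 6. Of the named genes, 16 of 81 calls with TCDD, 9 of 92 with Cl-BBQ and 3 of 3 between ligands were lost without some single array. Values near or below the floor of 4.31 limit fold changes. With vehicle this held for Gpr15, Cyp1b1, Cyp1a1, Ahrr, Itga2 and Ccr9, and Pltp and Nqo1 lay close to the floor. It also held for Cd22 and Popdc2 with either ligand, and for Stfa3 and Cybb with Cl-BBQ.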

Other observations

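The gene families in this part and the members named from them were chosen after the data had been seen, as were the tests on them. Histone genes fell with both ligands, 11 of 28 tested with TCDD and 15 of 28 with Cl-BBQ, with medians of -0.58 and -0.72 on the log2 scale, and none rose. Camera gave adjusted p of 9.0e-12 and 6.0e-11, and 0.0083 and 0.0083 with an estimated correlation. Centromere protein genes fell in 11 and 13 of 20 and none rose, with medians of -0.67 and -0.74 (camera, adjusted p = 1.2e-12 for both, and 0.0083 with an estimated correlation). Among 31 kinesin genes 12 fell with each ligand, such as the mitotic motors Kif11 and Kif20a, and 1 rose, Kif3a, a motor of the cilium. Their medians were -0.22 and -0.06 (camera, adjusted p = 2.8e-06 and 2.0e-06, and 0.013 for both with an estimated correlation). Kif11, Kif20a, Cenpe and Cenpf are also members of the G2 and M phase list. Of 60 cytosolic ribosomal protein genes, 0 were called by limma with TCDD, with 2 at an unadjusted p under 0.05, and Rps27 alone rose with Cl-BBQ. Of 79 respiratory chain genes, 0 were called by limma with TCDD, with 4 at an unadjusted p under 0.05, and Ndufa10 alone rose with Cl-BBQ. The ribosomal median was -0.02 with TCDD and 0.00 with Cl-BBQ, where quantile normalization or median centring turned its sign, and the respiratory chain medians were -0.03 and -0.04.

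Integrin genes moved in both directions. Itga2 and Itgae rose with both ligands, while Itgb1, Itga4 and Itgal, the alpha chain of LFA-1, fell, and with Cl-BBQ Itgb3 and Itgb7, the partner chain of Itgae, also rose. For the 15 integrins as a set no common shift was found (camera, adjusted p = 0.71 and 0.50). The interferon-induced transmembrane genes rose in 2 of 4 tested members with TCDD and 3 of 4 with Cl-BBQ, with medians of 1.47 and 1.71 (camera, adjusted p = 1.2e-04 and 2.0e-05, and 0.013 and 0.010 with an estimated correlation). Of the fixed list of 16 interferon-stimulated genes, which holds none of them, 0 were called by limma with either ligand, with 1 and 2 at an unadjusted p under 0.05.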
